A study of Bos taurus with 2 samples.

How the data were processed

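Whole blood total RNA from 2 Holstein specimens was labelled with Cy3 and hybridised to an Agilent bovine oligonucleotide array, 1 array each, per the labels. The labels give 1 sample of low and 1 of high feed efficiency, and do not say how many animals gave blood for a specimen.

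The deposited scanner files hold each spot's intensity at 532 nm. Per the file headers they were written by GenePix Pro 6.1.0.4 from a GenePix 4000B scanner, while the submitters' processing notes name Agilent Feature Extraction with no version. Both arrays came from 1 slide and 1 scan, per the file headers, so slide and scan do not separate the groups. The intensity used is the pixel median of a spot minus a background that the scanner software took from negative control spots, per the file headers. The percent of saturated pixels and a flag score of 100 (good), 0 (unflagged) or -50 (not found) come from the same deposited files. The planned signal was a column of Agilent Feature Extraction that these GenePix files do not have, so the background-subtracted pixel median took its place; the plan was otherwise kept.

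The authors' deposited value table holds log2 values with a median of 4.34 in both columns. Its values followed the rank order of the scanner intensities only when moved by 1 row: Spearman's rho with the scanner values was 0.077 and 0.072 for the low and high efficiency arrays as deposited, and 1.00 for both after the move (43652 rows). Across 10094 genes, the values of 2 probes of the same gene on the low efficiency array had a rho of 0.02 as deposited and 0.55 after the move. The table was used only as an alternative, after the move; its normalization is not given in the sources used here.

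Each array's 45220 spots held 43803 probe spots and 153 negative control spots. Control spots were left out, and spots flagged as not found although bright were left out on both arrays (408 in low, 283 in high feed efficiency), which kept 43096 probes. Intensities were divided by the array's 75th percentile over probes, 98 in low and 81 in high feed efficiency, and taken to log2. Spots of one probe were averaged. A probe counted as above background when its intensity exceeded the median of the negative controls by 3 robust SDs, which was 10.9 on both arrays; 56.5% of probes passed in low and 52.7% in high feed efficiency. A gene took the value of its brightest probe above background on both arrays, and other probes are given where they lay on the other side of 0 or, for a named gene 2-fold apart, under 2-fold. Saturated spots were kept (7 and 1 spots had saturated pixels).

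Probes were named through the RefSeq accession on the array and a gene table of the bovine assembly ARS-UCD2.0, used for names only. Of the probes, 26743 were named by accession, 5971 by a current symbol and 141 by a synonym; 1662 kept the array's name and 9136 had none and entered no gene comparison.

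The comparison was the log2 difference of low minus high feed efficiency, counted at 2-fold, with no test since each group had 1 array. For 23 gene lists and 9 lists of cell type markers, the median difference was set among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these 2 arrays. Lists, naming rule and the first alternatives below were fixed before the data were examined. Measurement error was described by the SD over replicate spots of one probe, pooled over 12 bright and 23 dim probes (above and below the median signal of genes), and by the range over probes of a gene. Between the 2 brightest probes of a gene, Pearson's r of the difference was 0.36 across 4995 genes, which are not independent replicates.

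Named genes were the 12 with the largest positive and the 12 with the largest negative difference among genes that had a symbol other than a placeholder, were above background on both arrays, had a mean signal above the median of detected genes, were not saturated on both arrays and had every detected probe on the same side of 0. Added were the 5 genes per direction with the largest bound among those above background on 1 array only. In each list, up to 3 members with the largest difference among those at least 2-fold apart were named, or else the member farthest from 0, and in marker lists also the 2 brightest members. The member this rule names in the thyroid hormone list is not reported here. For genes above background on 1 array only, the bound is the bright value over the higher of the other array's lowest detected signal and the probe's own signal there.

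Alternatives were normexp background correction of the pixel mean with an offset of 50, the pixel mean without background correction, scaling on the median of detected probes, quantile and loess normalization, the authors' table, 3 other filters on dim probes, the mean over probes, flagged spots kept, saturated spots left out, fold thresholds of 1.5 and 4, and random lists in 5 bins. Added after seeing the data were the pixel mean, scaling on 7 spike-in controls, centring in 30 regions of the array, and spots flagged good on both arrays. The spike-ins differed by -0.10 (SD 0.03) before scaling, against 0.27 for the 75th percentiles.

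On simulated data for this comparison over 10339 genes, with the noise of replicate spots, 100% of 50 genes set 4-fold higher and 100% of 50 set 4-fold lower passed 2-fold, and 0 of 10139 genes without a difference did. This noise held neither differences between specimens nor single aberrant spots. Its SD was also below that between probes of one gene (0.19 for bright and 0.30 for dim genes). The simulation therefore gives no rate of false calls for these arrays. Of 100 simulated lists of 25 genes without a shift, 96.0% lay inside the 95% range, and 100% of 25 lists shifted by 0.2 lay above it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 (normexp) were used.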

Results

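Gene expression was measured in whole blood of Holstein cattle (Bos taurus) with a bovine oligonucleotide microarray, on 1 array from a blood specimen of low feed efficiency and 1 array from a specimen of high feed efficiency. Residual feed intake is the feed an animal eats beyond what its size and production call for, so low feed efficiency stands for high residual feed intake. On each array 43653 distinct probes were read, of which 24329 lay above background in the low efficiency sample and 22718 in the high efficiency sample. The 22000 probes above background on both arrays gave a value for 10339 genes. All differences are log2 values of low minus high feed efficiency, and with 1 array per group they have no replicate check, no test and no p-value. The SD of the log2 difference over replicate spots of one probe was 0.10 for bright probes and 0.23 for dim ones. The number of arrays limits the precision.

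The comparison asks which genes of blood, and in particular which hormone-related genes, differ between cattle of low and high feed efficiency. Genes induced by interferon, the antiviral signal, were higher in low feed efficiency. Of 32 measured members 26 lay above the median of all genes, 1 was at least 2-fold higher, none was 2-fold lower and 31 lay between. Their median was 0.31 above that of all genes, at percentile 100 among 10000 random lists of like signal, whose 95% range ran from -0.12 to 0.10. IFIT2, which binds viral RNA, had a difference of 0.88 (intensity 1428 against 642), and OAS1X, of the family that senses double-stranded RNA, had 1.15 at intensities of 43 against 16 (0.33 with normexp background correction). ISG15 and MX1, widely used markers of interferon action that were chosen after their values were seen, had 0.16 and 0.26 (0.28 and 0.41 with normexp).

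Genes of MHC class II antigen presentation were lower in low feed efficiency relative to all genes. Besides BOLA class II genes, which present antigen to T cells, the list holds CD74, CIITA, CTSS, CTSH and IFI30. Of 15 measured members 14 lay below the median of all genes, 1 was at least 2-fold higher and 14 were less than 2-fold apart. The list median was -0.30 relative to all genes (percentile 0.12, random range -0.22 to 0.09), while the mean was 0.05, since a single member, BOLA-DQA5, was far higher by its measured value. BOLA-DQB counts among the 14 below, by its probe above background on both arrays. Other BOLA-DQB probes were far higher in low feed efficiency, at 1124 against 4 and 748 against 5. BOLA-DQA5 had intensities of 587 in low and 16 in high feed efficiency, a difference of 4.92 (2.93 with normexp), and its other probe read 866 against -2. Relative to all genes, BOLA-DQA2 had -0.54, the invariant chain gene CD74 -0.30 and BOLA-DRA -0.20; the unadjusted differences of CD74 and BOLA-DRA turned positive under spike-in scaling. These 3 were chosen after their values were seen. Unadjusted, BOLA-DRA had -0.24, but -0.55 with the pixel mean and -0.09 with loess, CD74 had -0.34 and -0.19 in the authors' table, and BOLA-DQA2 had -0.58 and -0.38 with normexp.

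**Figure D1:**
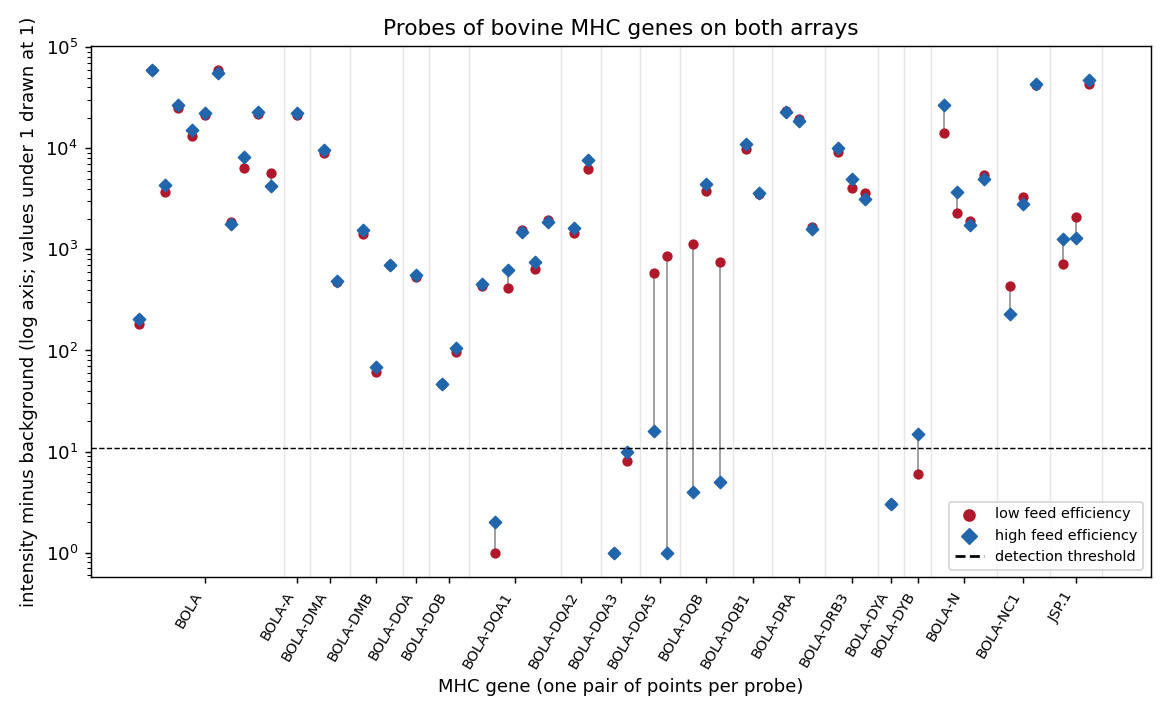
Background-subtracted intensity (log axis) of each probe of the bovine MHC genes, with a circle for the low and a diamond for the high feed efficiency array, 1 array each; values under 1 are drawn at 1 and the dashed line is the detection threshold. Both BOLA-DQA5 probes and 2 of the 3 BOLA-DQB probes were bright only in low feed efficiency, while the remaining BOLA-DQB probe read 3765 against 4393.

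Markers of blood cell types were also apart. Neutrophil markers had a median of 0.16 relative to all genes (percentile 99.7, range -0.15 to 0.11), with 20 of 26 above the median of all genes and none 2-fold apart. The calgranulin genes S100A12 and S100A8, the brightest of them, had 0.22 and 0.10 (0.43 and 0.19 in the authors' table); S100A9, chosen after its values were seen, had 0.13 and turned negative under 3 alternatives. The cathelicidin CATHL1, an antimicrobial peptide gene read near background at 38 against 16, had 0.97 (0.16 with normexp). Natural killer and cytotoxic cell markers had a median of -0.23 relative to all genes (percentile 0.47, range -0.18 to 0.13), with 12 of 16 below the median of all genes and none 2-fold apart. NKG7 had -0.65 and CCL5, a chemokine of cytotoxic cells, -0.43 over 3 probes that ran from -0.46 to -0.39; granzyme B (GZMB) had -0.18, which turned positive under spike-in scaling. Neutrophil, natural killer, interferon and class II lists stayed outside their random ranges under all 15 alternatives that did more than rescale an array.

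The other cell type lists lay inside their random ranges. Of their members above background on both arrays, all but ALAS2 were less than 2-fold apart by their brightest probe. FCGR1A, a monocyte marker, was above background only in low feed efficiency, at 64 against 4 (at least 4.81-fold higher). Median differences relative to all genes were -0.09 for 17 monocyte markers (percentile 30.8), -0.08 for 21 T cell markers (24.5), -0.09 for 20 B cell markers (13.5) and 0.10 for 4 gamma-delta T cell markers (73.3). They were 0.02 for 18 erythroid markers (71.3), -0.02 for 15 platelet markers (53.5) and -0.06 for 7 markers of eosinophils, basophils and mast cells (23.3). The macrophage growth factor receptor CSF1R had -0.86 with its 3 probes between -0.86 and -0.52, and the brightest monocyte markers, FCN1 and LYZ, had -0.41 and 0.32, while the other LYZ probe, in use when only spots flagged good were kept, had -0.05. Among T cell markers IL7R had 0.79 at 44 against 21 (0.36 with normexp), CD4 had -0.41 with its other probe at 0.17 (mean over probes -0.12), and CD247 had -0.17, which turned positive under spike-in scaling. SOX4 had 0.86 (0.46 with normexp), CD163L1 0.11 with 6 probes between -0.01 and 0.24, and GATA3 0.00, the last with either sign across alternatives. PAX5, a B cell transcription factor, had -0.55, while CD79A had 0.11 (other probe -0.33) and TNFRSF13C -0.05 (other probe 0.01), both with either sign across alternatives. ALAS2, the erythroid enzyme that starts heme synthesis, had -1.42 (112 against 248, -0.84 with normexp), whereas the globin genes HBA and HBG had 0.13 and 0.33 (0.28 for HBA with loess, 0.21 for HBG with spots flagged good). MYL9 had -0.58 with its other probe at -1.11, GNG11 0.22 with 3 probes between -0.04 and 0.22, and PF4 -0.05. The last 2 took either sign across alternatives. CCR3, the eotaxin receptor, had -0.80 and ALOX15 -0.10, which turned positive under some alternatives.

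Over all genes 38 were at least 2-fold higher and 59 at least 2-fold lower in low feed efficiency, and 99.1% were less than 2-fold apart. Scaling on the spike-in controls, which moved the median of all genes by 0.38, gave 231 higher and 20 lower instead. Using only spots flagged good on both arrays, with 8530 genes, gave 7 and 17, and brighter probes gave 7 and 20. With normexp 27 were higher and 42 lower, of which 6 and 13 were among the 38 and 59; the pixel mean gave 58 and 82, with 23 and 34 among them. Of the genes 2-fold higher, 15 had more than 1 probe and in 9 of these every probe lay above 0; of those 2-fold lower, 12 had more than 1 probe and in 7 every probe lay below 0. Every probe was at least 2-fold higher for 2 genes, PLAC8A and PGA5, and for no gene was every one of several probes 2-fold lower.

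PLAC8A had the largest positive difference among bright genes whose probes ran one way, 1.81 (3.51-fold, 399 against 94), with its 4 probes between 1.34 and 1.81. IFI47, an interferon-inducible GTPase gene, had 1.21 and PGA5, a pepsinogen gene, 1.03 over 2 probes (0.93 with normexp). Below 2-fold in this group were the RNA-binding protein gene YTHDF2 with 0.87, the trefoil factor gene TFF2 with 0.86, the death receptor gene FAS with 0.82, and CASP4, an inflammatory caspase gene, with 0.80 and 3 probes between 0.37 and 0.80. DHRS9 had 0.80 (other probe 0.26), MRPL33 0.80, GADD45G 0.78 and TMEM70 0.77.

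The largest negative difference in the same group was that of MLN, which encodes the gut hormone motilin, with -3.93 (39 against 490, a single probe whose bright spot was not flagged good) and -6.50 with the pixel mean. NCDN followed with -3.20, but its 3 probes ran from -3.20 to -0.22 (mean over probes -1.26). NANOS3 had -1.54 and a second probe at -0.18, C1QTNF6 had -1.53 and WBSCR27 -1.49, the last at intensities of 2471 against 5721. BOLA-N, an MHC class I gene, had -1.21 with 4 probes between -1.21 and -0.14 (mean over probes -0.62). ALAS2, described with the erythroid markers, also belonged here with -1.42. The remaining genes of this group were PUSL1 with -1.22 (-0.93 with normexp), EMC9 with -1.19 (-0.81 with spike-in scaling), KPNA6 with -1.14 (-0.76 with normexp), TSLP, a cytokine gene, with -1.04 (-0.67 with normexp) and FIBP with -1.01, whose other probe had -0.12. TSLP fell below 2-fold under 5 alternatives, BOLA-N under 6 and FIBP under 8. Of 18 named genes at least 2-fold apart, 7 stayed so wherever measured: PLAC8A, IFI47, MLN, NCDN, C1QTNF6, WBSCR27 and BOLA-DQA5. Beyond the naming rule, chosen after their values were seen, AHR (712 against 25) and RAB13 (163 against 30) were with BOLA-DQA5 the 3 genes at least 4-fold higher; the other detected RAB13 probe had -0.05, and the other AHR probe read 9 against 4, below background on both arrays. With the pixel mean AHR had 7.80 in place of 4.56 and RAB13 7.83 in place of 2.17, and as the mean over probes RAB13 had 1.06. ERG, at 11 against 725, was the lowest of 7 genes at least 4-fold lower, and its other detected probe had 0.05 (mean over probes -3.14 in place of -6.32).

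**Figure D2:**
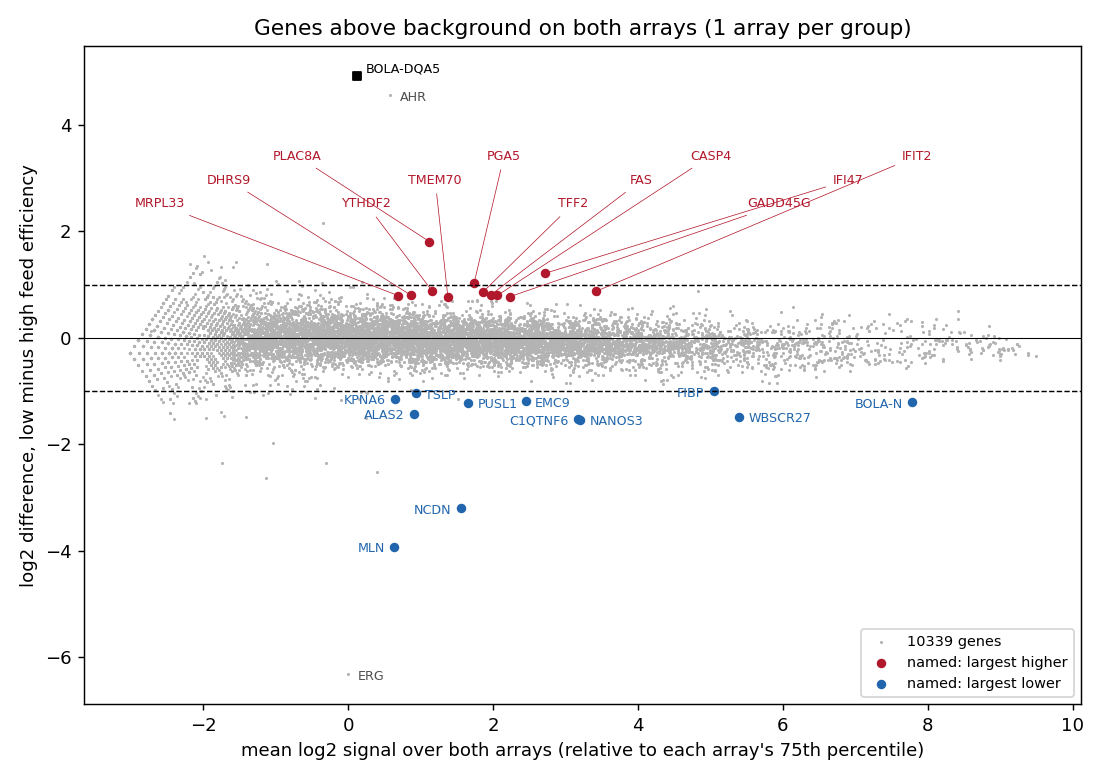
Log2 difference of low minus high feed efficiency (y axis) against the mean log2 signal over both arrays (x axis) for 10339 genes, 1 array per group; dashed lines mark 2-fold, colours mark the named genes and a square marks BOLA-DQA5. Most points lie between the dashed lines, with 38 genes at or above the upper and 59 at or below the lower line; spike-in scaling would raise every point by 0.38.

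Hormone lists, the subject of the study's title, lay inside their random ranges, though 3 of them did not under some alternatives. Growth hormone and IGF axis genes had a median of 0.05 relative to all genes over 18 members (percentile 73.1), none 2-fold apart, and STAT5A, which carries the growth hormone signal, was farthest from 0 with -0.64 (-0.38 with normexp). Another STAT5A probe went the other way, at 21 in low and 9 in high feed efficiency, the latter below background. Insulin signalling genes had 0.14 over 22 members (percentile 97.0), of which 1 was 2-fold higher, TSC1, an inhibitor of mTOR signalling, with 1.28 at 41 against 14 (0.23 with normexp background correction) and 0.62 at its other probe. Appetite and adipokine genes had 0.01 over 11 members (percentile 50.7), with galanin (GAL) at -0.42. Thyroid hormone genes had 0.13 over 13 members (percentile 91.4), and lay above their range under 3 of the 15 alternatives. Glucocorticoid receptor and induced genes had 0.05 over 19 members (percentile 82.9), with ZBTB16 at -0.60 (-0.21 with normexp); they lay above their range under 2 of the 15, with 0.32 among brighter probes. Steroid hormone genes had -0.11 over 15 members (percentile 8.74), with the estradiol-forming enzyme HSD17B1 at -0.80. Pituitary and reproductive hormone genes had -0.20 over 9 members (percentile 3.26), with the vasopressin receptor AVPR2 at -0.55, and lay below their range under 4 of the 15. Except in insulin signalling no measured member of these lists was 2-fold apart. Many members had no value: measured were 9 of 25 pituitary and reproductive, 11 of 28 appetite, 13 of 22 thyroid and 15 of 25 steroid genes. Of the growth hormone, insulin and glucocorticoid lists 18 of 27, 22 of 30 and 19 of 20 were measured.

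In energy and lipid metabolism no member above background on both arrays was 2-fold apart by its brightest probe. ACADL, of the fatty acid oxidation list, was above background only in high feed efficiency, at 1 in low against 21 (log2 bound 1.21). Another probe of the oxidative phosphorylation gene COX5A read 0 in low and 207 in high feed efficiency, on a spot not flagged good. Oxidative phosphorylation genes (79 measured) had a median of -0.003 relative to all genes, at percentile 98.5 since random lists of like signal ran from -0.13 to -0.01; the mean was 0.03, the median took either sign across alternatives, and it lay inside the random range under 8 of the 15. Its member farthest from 0 was COX6C with 0.47. Cytosolic ribosomal protein genes (76 measured) had -0.04, at percentile 99.5 of a random range from -0.18 to -0.06, with a mean of 0.01 and either sign across alternatives, and inside the range under 2 of the 15; RPL15 had 0.50, with 8 probes between -0.34 and 0.50, and a negative value when only spots flagged good were used. Medians relative to all genes were -0.10 for 25 citric acid cycle genes (percentile 10.9), -0.11 for 22 glycolysis genes (20.2), -0.01 for 22 fatty acid oxidation genes (46.4), 0.03 for 21 cholesterol synthesis genes (66.8) and -0.04 for 19 lipogenesis genes (31.6). The members farthest from 0 were DLST with -0.52 (-0.18 with normexp), the aldolase gene ALDOC with -0.41, the mitochondrial fatty acid importer CPT1B with -0.60, HSD17B7 with 0.68 and another probe at -0.56, and the desaturase gene FADS2 with -0.51 (-0.29 with normexp).

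Inflammation and stress lists had no measured member 2-fold apart and lay inside their random ranges. Inflammatory cytokine and chemokine genes had -0.04 over 14 members (percentile 29.6), and CXCL8, which attracts neutrophils, had -0.78 (-0.52 with normexp) with 3 probes between -0.94 and -0.70. Acute phase and endotoxin response genes had -0.09 over 14 members (percentile 20.2), with the endotoxin co-receptor LY96 at 0.69. Immediate early genes had 0.05 over 19 members (85.5), with FOSB at -0.73; heat shock and unfolded protein response genes had -0.04 over 24 members (55.1), with the co-chaperone BAG3 at -0.64 (-0.37 as the mean over probes). Proteasome genes had -0.07 over 36 members (33.0), with PSMB6 at -0.70, and antioxidant genes 0.003 over 20 members (72.6), with the mitochondrial superoxide dismutase SOD2 at 0.56. Cell cycle genes had -0.10 over 19 members (6.98), with CDK1 at 0.66, near background and of either sign across alternatives. In all, 6 of 32 lists lay outside their 95% range, and 4 of the 6 did so under every alternative that did more than rescale an array. Lists of genes that vary independently would give 1.6 on average. Genes of one list can vary together and some lists share members, so the 6 cannot be read as an excess over this number. Mean and median differed in sign relative to all genes for MHC class II, appetite, oxidative phosphorylation, ribosomal protein and erythroid lists.

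**Figure D3:**
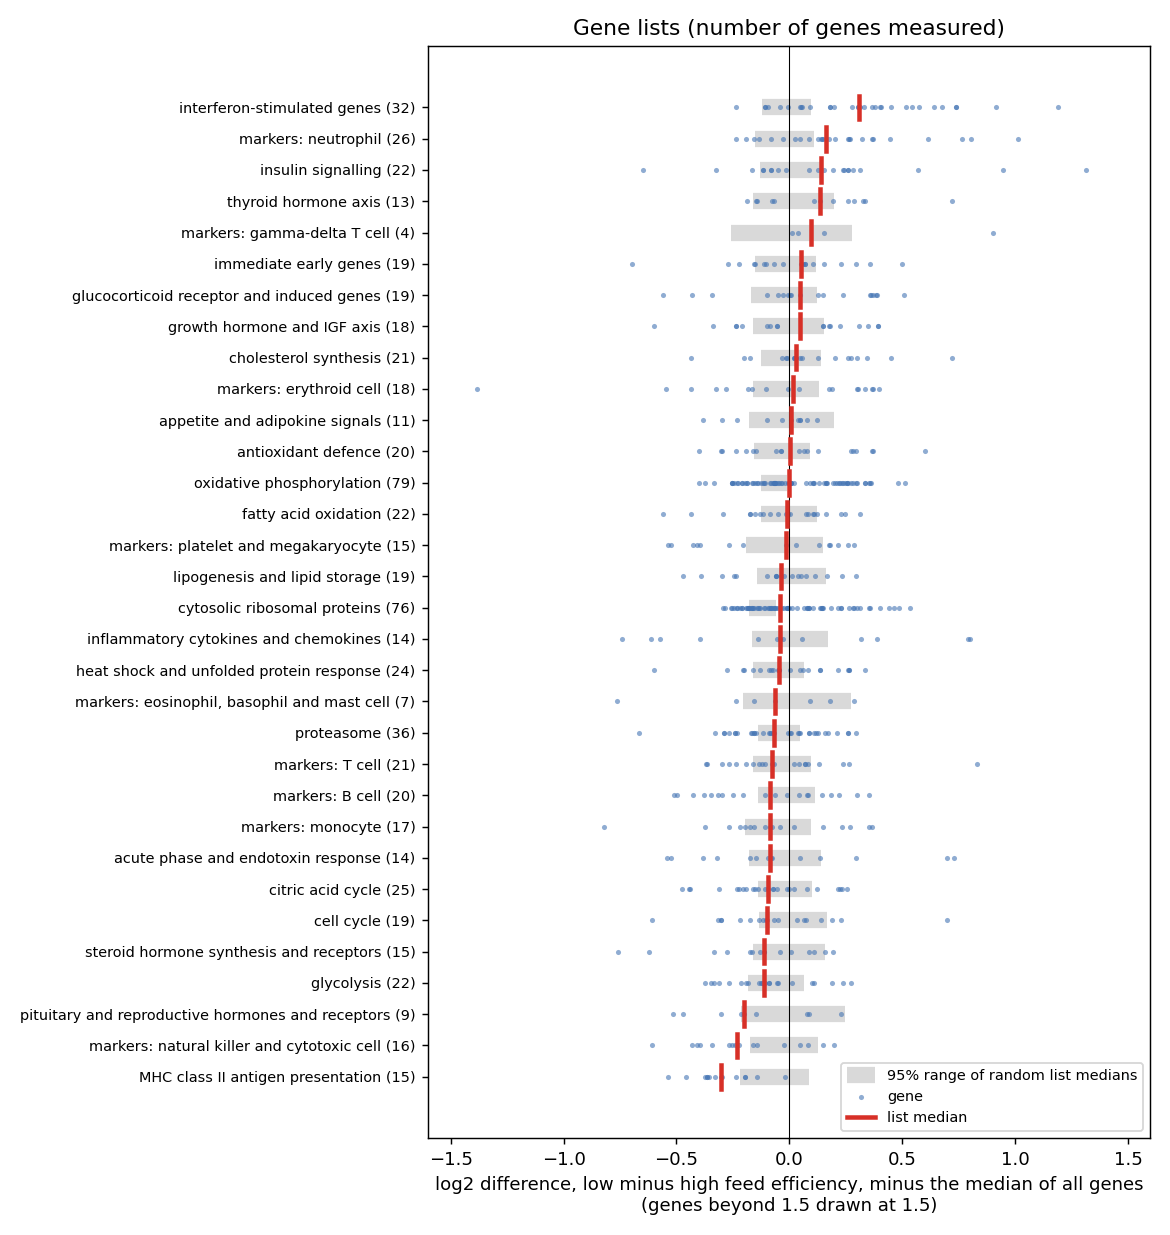
Log2 difference of low minus high feed efficiency relative to the median of all genes (x axis) for the genes of each list (points, 1 array per group), with the list median (red line) and the 95% range of the medians of 10000 random lists of like signal (grey). Interferon-stimulated genes lie farthest to the right with a median of 0.31 and MHC class II genes farthest to the left with -0.30; spike-in scaling cannot change these relative positions, and the lists of oxidative phosphorylation and ribosomal proteins took either sign across alternatives.

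Some genes were above background on 1 array only, 772 in low and 265 in high feed efficiency, and the bound reached 2-fold for 17 and 32 of these. The cut for background was 10.9 on both arrays before scaling, and the low efficiency array was brighter (75th percentile 98 against 81). The counts of 772 and 265 therefore cannot be read as more genes expressed in low feed efficiency. Above background only in low feed efficiency were ARHGAP44 (at least 15.6-fold higher), GOPC (at least 7.96-fold), DCLK1 (at least 5.64-fold), the cell cycle kinase gene MASTL (at least 5.49-fold) and FCGR1A, the high-affinity IgG receptor gene (at least 4.81-fold). Above background only in high feed efficiency were PCDHB6 (at least 26.3-fold higher), NT5E, which encodes CD73 (at least 10.3-fold), AVIL (at least 8.91-fold), HHATL (at least 6.93-fold) and POP1 (at least 4.62-fold). Each of these bounds rests on 1 probe: for the 7 of the 10 genes that had other probes, these were below background on both arrays, and none of the 10 bright spots was flagged good. With the pixel mean the log2 bound was over 1.5 times as large for 9 of the 10.

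With 1 specimen per group, a difference between the feed efficiency groups is not separable from a difference between these specimens. Genes at least 2-fold apart were mostly dim, with 3 of the 38 higher and 13 of the 59 lower ones in the brighter 5169 genes.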

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

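The 9136 probes without a gene name entered no gene comparison, yet 3627 of them were above the negative controls on both arrays. Of these, 20 were at least 2-fold higher and 20 at least 2-fold lower in low feed efficiency. Probe A_73_P160802 read 579 against 160 and probe A_73_P064896 read 223 against 536; these were singled out after their values were seen.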

How the results depend on the processing

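The medians of interferon-stimulated genes (0.22 to 0.33 relative to all genes), neutrophil markers (0.12 to 0.24), MHC class II genes (-0.34 to -0.20) and natural killer markers (-0.26 to -0.13) kept their direction and stayed outside the random range under 15 alternatives. Spike-in and detected-median scaling shift all genes alike and cannot move a list relative to all genes, and leaving out saturated spots, among the 15, hardly moved these. The pixel mean, spike-in scaling, array regions and good-flag settings were chosen after seeing the data. Of 72 named genes, 60 kept 1 sign under every alternative that measured them, and 2 of the others, CD247 and GZMB, turned only with the shift of all genes under spike-in scaling. The difference of 42 of the 72 moved by over 1.5 times under at least 1 alternative that did more than rescale an array. Which genes passed 2-fold depended on the signal used: with normexp, 6 of 27 higher and 13 of 42 lower genes were shared with the 38 and 59, and with the pixel mean 23 of 58 and 34 of 82. Of 18 named genes at least 2-fold apart 7 stayed so under every alternative that measured them, and for MLN and BOLA-DQA5 the good-flag setting gave no value. No paired analysis was possible because each group had 1 array.

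Counts of genes 2-fold higher and lower were 7 and 20 among brighter probes (6131 genes) and 7 and 17 among spots flagged good (8530 genes). All of these were among the 38 and 59 found over 10339 genes. The counts fell by a larger share than the genes kept, so most genes 2-fold apart rested on dimmer probes or spots not flagged good. With spike-in scaling the counts were 231 and 20, and 58 were higher with the pixel mean. Thresholds of 1.5-fold and 4-fold gave 277 and 325, and 3 and 7. Oxidative phosphorylation lay inside its random range at 0.072 with normexp, 0.024 without background correction, 0.041 with quantile normalization, 0.032 with loess, 0.04 in the authors' table, -0.0066 as the mean over probes, -0.034 with the pixel mean and -0.033 with regions centred. Ribosomal proteins did so at -0.061 as the mean over probes and at an unchanged -0.042 with 5 signal bins. Lists that came to lie outside were thyroid hormone genes at 0.14 with normexp, 0.18 without background correction and 0.20 with regions centred, and glucocorticoid genes at 0.11 with normexp and 0.32 among brighter probes. Pituitary hormone genes did so at -0.24 with quantile normalization, -0.23 with loess, -0.28 among brighter probes and -0.21 with spots flagged good, and cell cycle genes at -0.091 without a filter. RAB13 turned to -0.052 without saturated spots, another probe then giving its value. Beyond which probes were kept, the cause of these changes was not tested. Bounds of genes on 1 array were recomputed only where signal, scaling or flags alone differed.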

Other observations

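MHC class I probes, which no list covered, were lower in low feed efficiency as well. Over 22 probes of BOLA, BOLA-A, BOLA-N, BOLA-NC1 and JSP.1 the median difference was -0.31 relative to all genes, at percentile 0 among matched random lists of probes (range -0.19 to 0.04), and 19 of the 22 lay below the median of all genes. Of these probes 11 belonged to BOLA, and probes of one gene are repeated measures of it. The percentile and the count of 19 therefore do not rest on 22 independent values. The class I set was not planned, and it includes BOLA-N, which the naming rule had picked for its negative difference. Among antimicrobial peptide genes of neutrophils, the cathelicidins CATHL2 and CATHL4 had differences of 0.73 and 0.77. Both were close to background and had 0.11 and 0.07 with normexp background correction. TGM3, a transglutaminase gene with 4 probes between 0.37 and 0.58, had 0.58 at 8423 against 4670. CATHL2, CATHL4 and TGM3 were chosen after their values were seen.

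All tests below were chosen after the patterns they concern were seen; for array position, the prediction was written before the centred medians were computed. The higher level of interferon-stimulated genes was not removed by loess normalization, which left their median at 0.33 relative to all genes (bootstrap SE 0.07, random range -0.11 to 0.10), nor by centring each region of the array, which left 0.32 (SE 0.05, range -0.12 to 0.09). On these arrays, the values argue against a signal-dependent trend and a position effect as the whole cause. The bootstrap SEs and intervals here and below resampled the genes of a list. They treat these genes as independent, although genes of one list can vary together. They hold no spread between specimens or arrays, so they can be too narrow. A higher neutrophil share stays open. The interferon list exceeded the neutrophil markers by 0.15, with a 95% bootstrap interval over genes of -0.05 to 0.28. Feed efficiency itself and other differences between the specimens were not tested and cannot be separated with 1 specimen per group.

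The lower MHC class II and natural killer medians and the higher neutrophil median were set against the same explanations. After loess normalization they were -0.27 for class II and 0.24 for neutrophil markers, outside their random ranges by more than the bootstrap SE. Natural killer markers had -0.20, outside by less than the SE, so by this rule a signal trend is not excluded for them. Loess hardly moved their percentile, however, from 0.47 to 0.5. The random lists were matched on signal and so already carried such a trend. This limits what loess could show for these lists and for the interferon list. After centring array regions the class II, neutrophil and natural killer medians were -0.33, 0.17 and -0.25, all outside by more than the SE. A higher neutrophil share that dilutes all other leukocytes alike may account for part of the natural killer difference. The natural killer median lay -0.15 from the mean of T cell, B cell and monocyte medians. The 95% bootstrap interval of this distance, -0.29 to 0.07, includes equal dilution. For class II genes dilution was not tested. No cell counts were analysed here.

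Of 43096 probes, 6 were at least 10-fold higher in low feed efficiency, and 4 of these 6 belonged to BOLA-DQA5 and BOLA-DQB, whose products form class II DQ molecules. With 4 of their 5 probes apart, at separate spots, a defect at a single spot is excluded. The class II list had 14 measured members other than BOLA-DQA5, not all of them BOLA genes. Their median was -0.32 relative to all genes (95% bootstrap interval over these genes -0.37 to -0.22). This argues against a general class II level. BOLA-DQB itself counts among these 14, by its probe that was not apart (3765 against 4393). A candidate explanation is that the specimens carry different MHC haplotypes, of which some hold DQ genes that others lack or that bind these probes poorly. The test on class I probes left this open: the SD of their differences was 0.43, above the random range of 0.17 to 0.35, but their median absolute deviation was 0.15, inside its range of 0.08 to 0.24. An earlier test on the size of the class I differences, which lay above its random range, was set aside because the shared lower level of class I probes alone gives that.

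As deposited, with values not moved by 1 row, the authors' table would give 731 genes at least 2-fold higher and 969 at least 2-fold lower in low feed efficiency, against 32 and 73 after the move.

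Of the 15 probes at least 10-fold lower in low feed efficiency, 10 had a gene name, and for the 7 whose genes had another probe that probe was in 0 cases 2-fold lower. ERG, with 11 against 725, was among these, and MLN, with 39 against 490, had a single probe. Not every other probe could show such a drop: those of NT5E, also among the 7, lay below background on both arrays.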
